A study of Mus musculus with 8 samples.

How the data were processed

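Total RNA from mouse dorsal root ganglia at embryonic stage E12.5 was measured on Illumina bead arrays after biotin labelling, with 4 wild-type samples and 4 samples of the genotype Erk1/2CKO(Wnt1), called the Erk1/2 mutant here. Per the labels, the ganglia came from 3 independent litters, were dissected in buffer with RNAlater, frozen on dry ice and extracted with Trizol and a column kit. The labels do not say which sample belongs to which litter, nor whether a sample is 1 embryo or a pool. With 4 samples in each group and 3 litters, some samples share a litter. All 8 arrays lay on 1 slide, the wild-type samples in its first 4 positions and the mutant samples in its last 4, so position on the slide and genotype cannot be told apart.

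The deposited table of bead intensity holds 25697 probes on a linear scale with 1 column per sample. BeadStudio is the only tool the labels name, without a version or settings. The values never fall below 80.3, so no background had been subtracted, and the table carries neither detection p-values nor control probes. The authors' processed table, in log2 units, was checked against these intensities: log2 followed by quantile normalization of the deposited intensities gives it back with a largest difference of 5.0e-09, and every column has a median of 7.21. Scale, centring and direction of that table are therefore settled, and it serves as an alternative.

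The plan fixed before the data were examined was neqc where detection p-values or control probes were given, and otherwise normexp with an offset of 50 followed by quantile normalization; the second was needed. Intensities were background corrected with normexp (offset 50), quantile normalized between arrays and put on the log2 scale with limma 3.58.1 in R 4.3.3. The offset pulls the log2 differences of dim probes towards 0. Probes were named from the platform annotation through their Entrez gene identifiers and the gene symbols of the GRCm38.p6 annotation, used for names and for gene order only. Of the 25697 probes, 23978 have 1 gene symbol, 0 have several and 1719 have none in the table used; 23962 symbols were matched by identifier and 16 were kept from the annotation. The genes named in the genotype carry no probe name in that table and were not analysed here, so the labels could not be checked on the deleted genes.

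Probes whose mean over the 8 arrays was above the median of all probes (log2 intensity of 6.71) were kept, 12848 in number. The probe with the highest mean over the 8 arrays stood for each gene, which left 9664 features, of which 8935 are named genes and 729 unnamed probes. Each feature was tested with limma (lmFit and eBayes, two-sided), mutant minus wild-type, with no covariate, and p-values were adjusted by Benjamini-Hochberg over the 9664 features. A gene was called at an adjusted p under 0.05, and counts of genes leave out unnamed probes. Errors of log2 differences are standard errors of the fit with n = 4 per group, and SDs are between the 4 arrays of a group. The number of arrays limits the precision; the median standard error over all genes was 0.10.

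The lists of genes were fixed before the data were examined. They cover transcriptional outputs and components of the ERK pathway, glial, neuronal and neural crest markers, growth control and metabolism, and markers of other tissues that dissected ganglia could carry. The 22 lists with at least 4 tested members, sex-linked genes left out, were tested with camera at a preset correlation of 0.01 and adjusted over the 22 lists. Camera with the correlation estimated per list and fry, the rotation test of direction, were run as alternatives. The genes named in the text follow a rule fixed at the same time. It takes the 12 largest differences in each direction among called genes whose 4 mutant arrays all lie on one side of the 4 wild-type arrays. From each list it takes up to 4 called members with the smallest adjusted p, or the 2 brightest members where none was called. Further genes named below were chosen after their values were seen.

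The procedure was tested on simulated data of 9664 features and 8 arrays. It recovered 81.0% of genes changed 1.5-fold, 97.9% of genes changed 2-fold and 99.4% of genes changed 3-fold, and 4.14% of its calls were unchanged genes. In 20 of 20 simulated runs camera called the shifted list, with 2 unshifted lists called over all runs. The simulated genes and arrays varied independently, with no litters. In the real data the correlation estimated per list ran from -0.10 for autonomic genes to 0.84 for cell cycle genes. These rates therefore do not carry over to lists whose genes vary together, nor to samples that share a litter. The alternatives were no background correction, the authors' table, cyclic loess, median scaling, no filter, a filter at the upper quartile, the mean of a gene's probes, an intensity trend, array weights, the replicate number as a block, a sex score as a covariate, other thresholds, and leaving out each array. Without wild-type replicates 3 and 4, without wild-type replicates 1 and 2, and an erythroid score as a covariate were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.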

Results

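Gene expression was measured in dorsal root ganglia of mouse embryos at embryonic stage E12.5, in 4 wild-type samples and 4 samples from Erk1/2CKO(Wnt1) embryos. In this genotype Erk1/2, the terminal kinases of the ERK/MAPK cascade, are removed with Wnt1-driven Cre, which acts in the neural crest, the origin of both the neurons and the glia of these ganglia. The median raw bead intensity was 144 to 159 on the wild-type arrays and 138 to 147 on the mutant arrays. The wild-type arrays fell into pairs. Replicates 1 and 2 correlated at r = 0.994 across genes and replicates 3 and 4 at r = 0.993, against 0.9749 to 0.981 between the pairs; genes are not independent replicates. The first principal component, 41.8% of the variance, set wild-type replicates 3 and 4 (25.7 and 21.1) apart from the other 6 arrays (-3.02 to -12.2).

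The single comparison the design names asks which genes differ between mutant and wild-type ganglia. Of 17 tested transcriptional outputs of the ERK pathway 6 fell in the mutant, 0 rose and 11 did not pass; as a list they were lower by camera (adjusted p = 1.6e-05), but not with an estimated correlation (adjusted p = 0.164). Etv4, an ETS transcription factor induced through ERK, fell by a log2 difference of -1.75 ± 0.13 (SE, n = 4 per group; limma adjusted p = 1.4e-04), Egr2 by -1.498 ± 0.10 (adjusted p = 8.3e-05) and Dusp6, a phosphatase that acts on ERK, by -0.91 ± 0.11 (adjusted p = 0.00445). Egr2 also drives the myelin programme of Schwann cells and marks boundary cap cells. Tlx3, a transcription factor of sensory neurons, rose by 0.75 ± 0.12 (adjusted p = 0.0108). In all, 224 of 8935 genes passed the test, 125 of them higher and 99 lower in the mutant. Of these, 8 were at least 2-fold higher and 15 at least 2-fold lower.

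The largest falls included Plk1, a mitotic kinase, at -2.99 ± 0.61 (limma adjusted p = 0.0354, n = 4 per group), Cldn34c1, a claudin-family gene, at -1.88 ± 0.11 (adjusted p = 2.5e-05), and Uts2b, a urotensin-family peptide precursor, at -1.71 ± 0.28. The actin-associated LIM protein gene Pdlim1 (-1.62), Tmem68 (-1.499) and Ctse, an aspartic protease gene (-1.47), fell as well. The potassium channel beta subunit gene Kcnab1 fell by -1.52 at its brightest probe, and by -1.39 and -0.22 at its others. So did Plekhb1 (-1.44), the netrin gene Ntn5, expressed by boundary cap cells (-1.36), and Alox12, a lipoxygenase gene (-1.24). Another probe of Alox12, under the filter level, differed by -0.06. Etv4 and Egr2 complete these 12. The 4 mutant arrays of Cldn34c1, Etv4, Uts2b, Egr2 and Ctse all lay under the filter level of 6.71, as did 3 of the 4 for Plk1. The exception for Plk1 was mutant replicate 3 at 9.52. Plk1 was no longer called without wild-type replicates 3 and 4 (-2.49, adjusted p = 0.126), nor without wild-type replicate 2, 3 or 4 or mutant replicate 1, 2 or 4 (adjusted p = 0.0536, 0.0873, 0.102, 0.1203, 0.109 and 0.0731). Uts2b and Ctse lost the call without mutant replicate 1 (adjusted p = 0.0555 and 0.0635) or 2 (0.0504 and 0.0648), Pdlim1 without wild-type replicate 4 (0.0533) or mutant replicate 1 (0.0703), and Tmem68 without wild-type replicate 4 (0.0572) or mutant replicates 1 or 2 (0.0584 and 0.0610).

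Among the largest rises, Hbb-b2, an adult beta globin gene, rose by 2.46 ± 0.13 (limma adjusted p = 1.5e-05, n = 4 per group). Its sequence is close to that of other beta globin genes, so which copy was measured is uncertain. Ccl19, a chemokine gene, rose by 2.00 ± 0.09 (adjusted p = 9.8e-06), Tmem25 by 2.12 ± 0.18 and Atp2c1, a calcium pump gene of the secretory pathway, by 2.17 ± 0.23. Tmem25 and Ccl19 lay under the filter level on 4 of 4 wild-type arrays and Atp2c1 on 3. Tmem87a rose by 1.76, the ribonuclease gene Rnase4 by 1.63, Mbp, a myelin protein gene, by 1.27, the cadherin-related gene Cdhr1 by 1.17 and the glycolytic enzyme gene Pkm by 0.99. The transporter gene Slco4a1 rose by 0.93, Cplx2, a regulator of synaptic vesicle release, by 0.93 and Mgp, an extracellular matrix gene, by 0.91. Some of these rises rest on 1 probe. The other probes of Tmem25, both under the filter level, differed by -0.0097 and -0.17, and that of Rnase4, also under it, by 0.15. As the mean of its probes Atp2c1 rose by 1.09 (adjusted p = 0.00559), Mbp by 0.75 (adjusted p = 0.0413) and Slco4a1 by 0.49 without a call (adjusted p = 0.0600); the second probe above the filter differed by -0.00026 for Atp2c1 and 0.039 for Slco4a1, and the other 2 of Mbp by 0.52 and 0.48. Without wild-type replicates 3 and 4, Tmem68 (-1.44), Tmem87a (1.41), Mbp (0.98), Slco4a1 (0.68), Cplx2 (0.64) and Mgp (0.55) kept their direction and lost the call (adjusted p = 0.0675, 0.138, 0.158, 0.0562, 0.0695 and 0.0708). Leaving out single arrays also ended the call of Tmem87a (wild-type 1, 3 or 4, mutant 1, 2 or 3; adjusted p = 0.0769 to 0.113), Mbp (any wild-type, mutant 1 or 2; 0.0568 to 0.133), Slco4a1 (wild-type 4, mutant 1, 2 or 3; 0.0577 to 0.0865), Cplx2 (wild-type 3 or 4, mutant 1, 2 or 3; 0.0531 to 0.0982) and Mgp (the same 5 arrays; 0.0869 to 0.119).

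**Figure D1:**
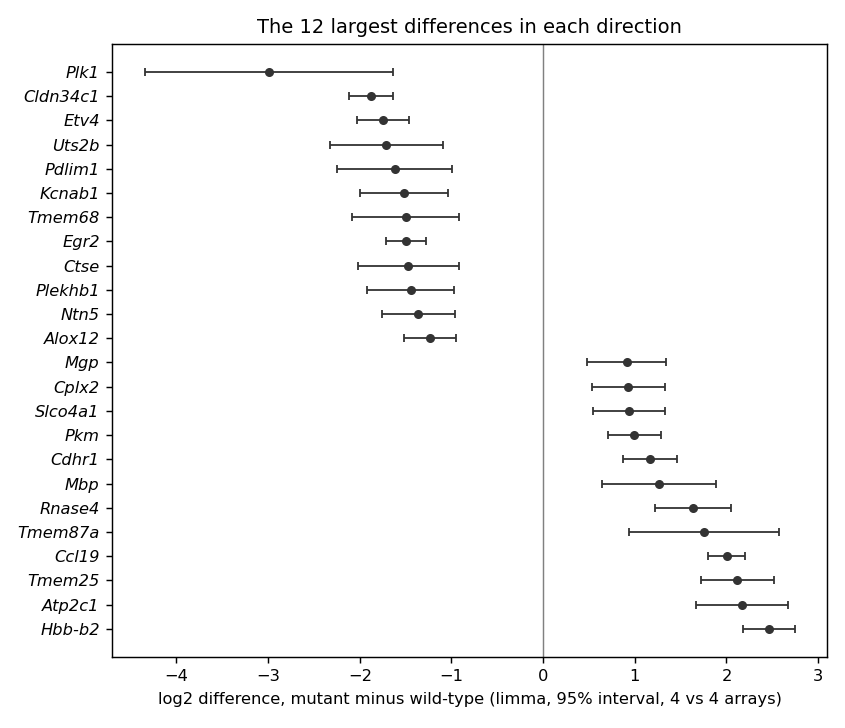
The 24 genes with the largest differences, as log2 difference between mutant and wild-type (points) with 95% intervals from limma, 4 arrays per group. Plk1 at -2.99 has the widest interval, and Hbb-b2 at 2.46 is the highest.

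All 224 called genes had mutant and wild-type arrays that did not overlap, which a low p with 4 arrays per group makes likely. Over all genes tested 1068 (11.95%) were separated in this way, against 2.86% if the arrays were interchangeable. Genes vary together and samples share litters, so setting these shares side by side is not a test. Leaving out 1 array moved the count of called genes by over 1.5 times for wild-type replicate 3 (128), wild-type replicate 4 (89), mutant replicate 1 (67) and mutant replicate 2 (79). Without both wild-type replicates 3 and 4 there were 212 called genes, 86 higher and 126 lower, of which 111 were among the 224. Without wild-type replicates 1 and 2 there were 1218, 610 higher and 608 lower, of which 210 were among the 224. A set of 61 genes, 27 higher and 34 lower, was called whichever single array was left out, and also without either wild-type pair; it holds Etv4, Egr2, Dusp6, Etv1, Spred1, Ntn5, Tlx3 and Ccl19, but not Dusp4. The split between higher and lower depends on scaling: 44.2% of calls were lower with quantile normalization and 76.0% (181 of 238) when each array was scaled to its median only, which moved the median difference of all genes to -0.06.

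Besides Egr2, Etv4 and Dusp6, the ERK pathway outputs that fell were Etv1, an ETS factor also needed by proprioceptive neurons, at -0.94 ± 0.12 (adjusted p = 0.00498), and the pathway inhibitors Spred1 at -0.62 ± 0.09 and Dusp4 at -0.71 ± 0.14 (adjusted p = 0.00915 and 0.0304). Adjusted over the list alone, 8 were lower and 1, Dusp14 at 0.39, was higher. Differences were negative for 14 of the 17. Etv5, Spry4 and Il17rd, commonly used readouts of the same pathway, stood at -0.04 ± 0.16, -0.19 ± 0.16 and -0.02 ± 0.09 and did not pass. The list's mean difference was -0.42, lower by camera (adjusted p = 1.6e-05; adjusted p = 0.164 with an estimated correlation) and by fry (adjusted p = 0.00235). Its level per array was 0.21 ± 0.09 (SD, n = 4) in the wild-type and -0.21 ± 0.06 in the mutant. Without wild-type replicates 3 and 4 the mean was -0.47 (adjusted p = 3.9e-06). The components of the cascade did not follow: 0 of 21 passed, with a mean of 0.03, Nras at -0.05 ± 0.08 and Shc1 at 0.12 ± 0.11.

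**Figure D2:**
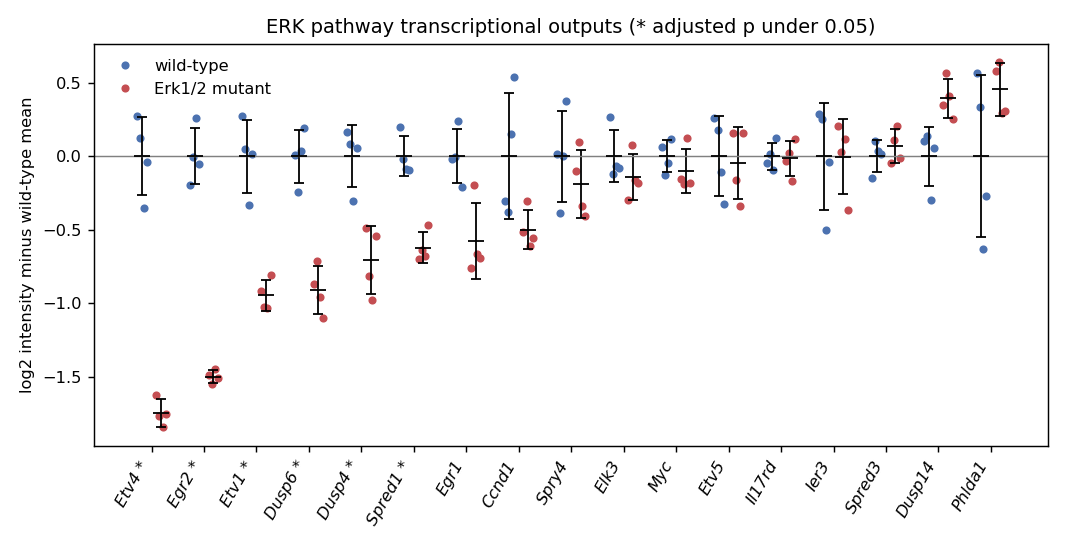
Log2 intensity of each ERK output gene on the 8 arrays, relative to the wild-type mean of that gene; black bars are group mean and SD (n = 4 per group), and stars mark the 6 called genes. The 6 starred genes are all lower in the mutant, from -0.62 for Spred1 to -1.75 for Etv4.

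Glial markers were mixed. Of 16 tested markers of Schwann cell precursors and satellite glia, 2 fell (Egr2, and Art3 at -0.68 ± 0.13, adjusted p = 0.0328), 1 rose (Mbp, 1.27 ± 0.28, adjusted p = 0.0459) and 13 did not pass. Adjusted over the list alone, 4 were lower and 1 was higher. Dhh, a signal from Schwann cell precursors to the nerve sheath, stood at -0.86 ± 0.20 (adjusted p = 0.0525) and Fabp7, a lipid-binding protein of early glia, at -0.52 ± 0.19 (adjusted p = 0.188). The progenitor gene Sox2 stood at 0.03 ± 0.12. The list's mean of -0.21 was called lower by camera (adjusted p = 0.0176), but not by fry (adjusted p = 0.144) and not by camera with an estimated correlation (adjusted p = 0.666). Mutant replicates 3 and 4 stood at 0.22 and -0.36 for this list, and at 0.92 and -0.50 for macrophage markers. Art3 lost its call without any single array but wild-type replicate 2 (adjusted p = 0.0523 to 0.103). The mean was -0.32 without mutant replicate 3. The call was lost without mutant replicate 4 (-0.13, adjusted p = 0.163) or wild-type replicate 1 (-0.18, adjusted p = 0.0530) and under median scaling (-0.29, adjusted p = 0.0648), and the sign turned with the filter at the upper quartile (0.035, adjusted p = 0.712). The mean was -0.31 (adjusted p = 0.0174) without wild-type replicates 3 and 4, and -0.11 without replicates 1 and 2, where the call was lost (adjusted p = 0.144).

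Of 27 pan-neuronal and sensory neuron markers, 1 rose (Tlx3), 0 fell and 26 did not pass; adjusted over the list alone, 4 were higher. The other 3 were Elavl3, an RNA-binding protein of neurons (0.48 ± 0.14), Neurod1, a neurogenic transcription factor (0.47 ± 0.14), and Nefh, the heavy neurofilament (0.46 ± 0.14), with adjusted p over all genes of 0.101, 0.111 and 0.116. Isl1 and Pou4f1, transcription factors that define sensory neurons, differed by 0.10 ± 0.10 and 0.17 ± 0.13. The list's mean of 0.16 was called higher by camera (adjusted p = 0.00947), but not with an estimated correlation (adjusted p = 0.731) or by fry (adjusted p = 0.359). The level of this list was -0.34 and -0.20 on wild-type replicates 3 and 4, against 0.13 and 0.10 on replicates 1 and 2, and erythroid markers stood at 0.66 and 0.28 on the former. Without replicates 3 and 4 the mean turned to -0.035 (adjusted p = 0.954), while Tlx3 kept its rise (0.70, adjusted p = 0.0456); without replicates 1 and 2 the list's mean was 0.35 (adjusted p = 9.1e-06). The call was also lost without wild-type replicate 3 alone (0.070, adjusted p = 0.175) and without mutant replicate 4 (0.09, adjusted p = 0.131). With the erythroid level as a covariate the list's mean was 0.031, and camera did not call it (adjusted p = 0.465).

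All 26 cell cycle genes had negative differences, but 1 passed the test, Plk1; adjusted over the list alone, Cdk1, the kinase that starts mitosis (-0.71 ± 0.19), passed too. The list's mean was -0.53, called lower by camera (adjusted p = 1.1e-07) but not with an estimated correlation (adjusted p = 0.666) or by fry (adjusted p = 0.304). The level of the list was 0.75 and 0.62 on wild-type replicates 3 and 4, -0.17 and -0.14 on replicates 1 and 2, and -0.19 to -0.32 on the mutant arrays. The mean without replicates 3 and 4 was -0.11 (adjusted p = 0.517). Over the 25 genes other than Plk1 it was -0.43 on all arrays and -0.017 without those replicates (adjusted p = 0.698). The mean of the whole list without replicates 1 and 2 was -0.95 (adjusted p = 1.5e-21). Erythroid markers moved with it: their level was 0.66 and 0.28 on wild-type replicates 3 and 4, and -0.32 to -0.06 on the other 6 arrays, with 0 of 11 called and a mean difference of -0.27 (camera adjusted p = 0.196). This mean was -0.43 and called without wild-type replicate 2 (adjusted p = 0.0122), -0.099 without wild-type replicate 3 (adjusted p = 0.704) and -0.60 without wild-type replicates 1 and 2 (adjusted p = 0.00226). With the erythroid level as a covariate the cell cycle mean was -0.25 ± 0.13 (SE over array means), and -0.15 ± 0.12 without Plk1. Camera called both (adjusted p = 0.00304 and 0.00671) at its preset correlation of 0.01, while the estimate for this list over all arrays was 0.84. The adjusted p-values of this list without a wild-type pair rest on the same preset.

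**Figure D3:**
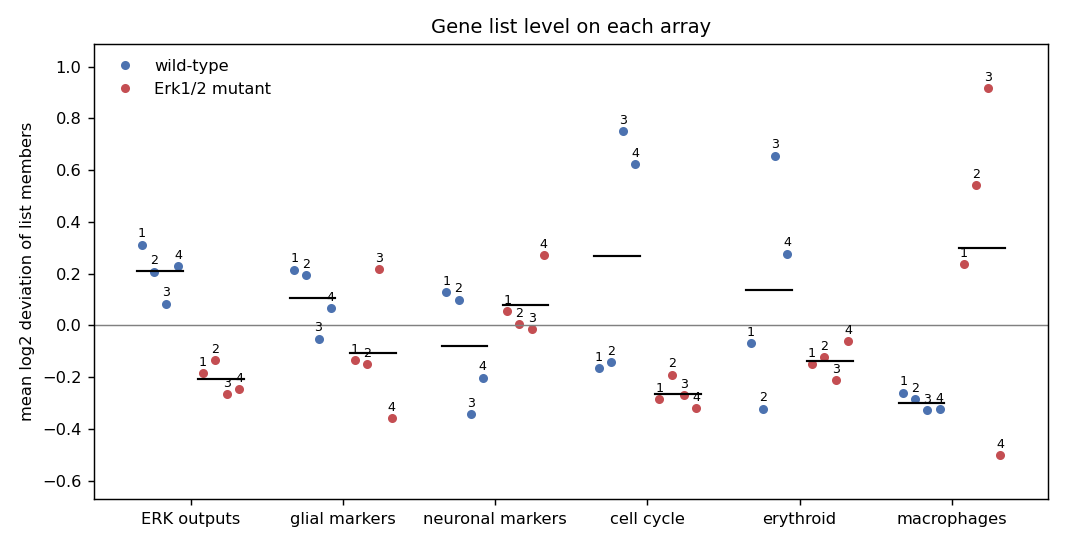
Mean log2 deviation of the members of 6 gene lists on each array, from the mean of the 2 groups; numbers are replicates and lines are group means (n = 4). ERK outputs separate the groups on every array, whereas the cell cycle level of the wild-type is raised by replicates 3 and 4 (0.75 and 0.62), and the macrophage level of the mutant spans -0.50 to 0.92.

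Neuronal subtype markers gave few calls. Among 11 mechanoreceptive and proprioceptive markers Etv1 fell, and 10 did not pass; Ret stood at -0.71 ± 0.23, and with it 2 were lower and 1, Nefh, was higher adjusted over the list alone. None of 7 nociceptive markers passed, 0 of 7 also adjusted over the list alone, with Gal, a neuropeptide gene, at 1.57 ± 0.77 and the ATP-gated channel gene P2rx3 at 0.15 ± 0.14; by the unadjusted limma p, 1614 of the 8935 genes lay under 0.05. The list level was -0.94 and -0.67 on wild-type replicates 3 and 4 and 0.43 and 0.46 on replicates 1 and 2. Of 5 autonomic genes 1 fell, Ddc, an enzyme of dopamine and serotonin synthesis, at -0.56 ± 0.11 (adjusted p = 0.0262); adjusted over the list alone 2 were lower and 1 was higher. Ddc was not called without wild-type replicates 3 and 4 (-0.41, adjusted p = 0.0684), nor without wild-type replicate 3 or 4 or mutant replicate 1, 2 or 3 (adjusted p = 0.0577 to 0.0884). That list's mean (0.15) and median (-0.05) differ in sign, and camera read it as lower (adjusted p = 0.622). Neural crest and progenitor markers (0 of 12, mean -0.04, camera adjusted p = 0.758; Vim 0.07 ± 0.10, Zic1 0.05 ± 0.17) and Notch pathway genes (0 of 13, mean 0.02, median -0.02, camera adjusted p = 0.854; Hey1 -0.03 ± 0.10, Hes6 0.20 ± 0.17) gave no call over all genes; adjusted over the list alone 1 Notch gene was higher. The Notch list without wild-type replicates 3 and 4 was called higher (0.17, adjusted p = 0.0261), with Hes6 at 0.52 (adjusted p = 0.0427). Without replicates 1 and 2 in their place, the nociceptive list was called higher (0.99, adjusted p = 0.00556), with Gal at 3.23 (adjusted p = 5.9e-04) and P2rx3 at 0.40 (adjusted p = 0.0356), and the neural crest list lower (-0.28, adjusted p = 0.0318). These signs turned without replicates 3 and 4, with no call: the nociceptive list stood at -0.26 (adjusted p = 0.114), Gal at -0.08 (0.853), P2rx3 at -0.10 (0.629) and the neural crest list at 0.20 (0.0806).

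Among growth factor receptors and ligands, 1 of 12 passed: Nrg1, the axonal signal on which Schwann cell precursors depend, fell by 0.41 (SE 0.08, limma adjusted p = 0.0354). The mean (-0.04) and median (0.06) of that list differ in sign (camera adjusted p = 0.742). Of 18 p53 and apoptosis genes 1 rose, the pro-apoptotic Bbc3, by 0.61 ± 0.13 (adjusted p = 0.0453; list mean 0.13, camera adjusted p = 0.291). Of 18 glycolysis and hypoxia genes 2 rose, Pkm and the stress-induced Ddit4 (0.66 ± 0.13, adjusted p = 0.0328; list mean 0.16, camera adjusted p = 0.0573). Camera called the glycolysis list higher without mutant replicate 4 (0.23, adjusted p = 0.00183) or wild-type replicate 1 (0.22, adjusted p = 0.00820), and with an adjusted p of 0.0202 to 0.0464 without a filter, with the filter at the upper quartile, with an intensity trend or with array weights. Without wild-type replicates 3 and 4, Nrg1 (-0.38), Bbc3 (0.43) and Ddit4 (0.53) were not called (adjusted p = 0.106, 0.138 and 0.116), and Pkm was (1.16, adjusted p = 0.00468). Single arrays ended these calls too: Nrg1 without any but wild-type replicate 1 (adjusted p = 0.0532 to 0.109), Bbc3 without wild-type 3 or 4 or any mutant array (0.0704 to 0.133), and Ddit4 without wild-type 2, 3 or 4 or mutant 1, 2 or 3 (0.0505 to 0.105). Adjusted over the list alone, these 3 lists had the same counts. Cholesterol synthesis genes had a mean of 0.15 with 0 of 15 members passing; camera called the list higher (adjusted p = 0.0141), fry did not (adjusted p = 0.249), nor did camera with an estimated correlation (adjusted p = 0.666). That call was lost without wild-type replicate 3 (0.12, adjusted p = 0.0702) or mutant replicate 4 (0.11, adjusted p = 0.110), without wild-type replicates 1 and 2 (0.16, adjusted p = 0.0805), with the filter at the upper quartile (0.12, adjusted p = 0.127) and under median scaling (0.068, adjusted p = 0.0544). Its brightest members were Hmgcs1 (0.12 ± 0.10) and Fdps (0.24 ± 0.11). Of 7 immediate early genes 0 passed, and adjusted over the list alone Egr1 (-0.58 ± 0.14) was lower and 2 were higher (Jund 0.41 ± 0.10, Klf6 0.27 ± 0.09, called without wild-type replicates 1 and 2 at 0.38, adjusted p = 0.0380); the list's mean was 0.14 (camera adjusted p = 0.159) and Dusp1 stood at 0.14 ± 0.11.

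Macrophage markers were higher in the mutant as a list, with a mean of 0.60 (camera adjusted p = 3.9e-04; adjusted p = 0.666 with an estimated correlation; fry adjusted p = 0.302). The call was lost with the filter at the upper quartile (0.52, adjusted p = 0.0913), and the mean was 0.39 without mutant replicate 3 (adjusted p = 0.00480). All 11 differences were positive and 0 passed; the brightest were Laptm5 at 0.43 ± 0.22 and Fcer1g at 0.48 ± 0.24, which were called without mutant replicate 4 (0.68 and 0.74, adjusted p = 0.0304 and 0.0289). The list stood between -0.33 and -0.26 on the wild-type arrays, and at 0.24, 0.54, 0.92 and -0.50 on mutant replicates 1 to 4. The globin genes Hba-a1 and Hbb-y were close to the top of the scale in both groups and differed by 0.07 ± 0.09 and 0.09 ± 0.07. No member was called among 14 endothelial (mean 0.01; Ramp2 -0.17, Egfl7 0.01), 17 mesenchymal and meningeal (0.08; Dcn 0.05, Pdgfra 0.16), 5 cartilage (-0.18; Sox5 -0.35, Col2a1 -0.17), 7 skeletal muscle (-0.05; Myl1 -0.30, Tnnc1 0.10) and 16 nerve matrix genes (-0.01, which camera read as higher; Col18a1 -0.14, Col4a1 0.22), with camera adjusted p = 0.827, 0.622, 0.2001, 0.900 and 0.900. Sox5 and Col2a1 were called lower without wild-type replicates 1 and 2 (-0.66 and -0.61, adjusted p = 0.00318 and 0.0156), and stood at -0.04 and 0.27 without replicates 3 and 4 (adjusted p = 0.887 and 0.314). The 2 spinal cord genes tested, Irx3 and Nkx6-1, stood at 0.22 ± 0.23 and 0.30 ± 0.22; Nkx6-1 was called higher without wild-type replicates 3 and 4 (0.74, adjusted p = 0.0170) and with the erythroid level as a covariate (0.62, adjusted p = 0.0221). Of the melanocyte genes 0 were bright enough to test.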

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

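Of the tests in this part, the mean of the cell cycle list with the erythroid score, its means without Plk1 and the gap of the other cell cycle genes between mutant arrays were chosen after the result was seen. A sample is named below where its distance to the nearest of the other 3 arrays of its group was large against the group's range. This applied to 13 of 172 groups of 4, where chance alone gives about 8.6.

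The first pattern is the set of 224 genes called between mutant and wild-type. There are 35 ways to split the 8 arrays into 4 and 4. The real split gave 224 called genes, and the highest other split gave 1. This cannot exclude chance, as the lowest share the test can give is 1 of 35. A real group difference would also widen the spread within every other split, which lowers their counts. The test takes arrays as interchangeable, but samples share litters, so an uneven spread of litters between the groups stays open. Sequence linked to the deleted genes was tested on gene order, within the 200 nearest genes on either side and no further. Of the 24 genes with the largest differences 1, Plk1, lies there, where 0.54 were expected from the share of tested genes. This argues against such nearby sequence as the source of most of the 24, though not for Plk1 itself. It says nothing about sequence further from the deleted genes. Over all called genes the share among those neighbours was 0.79 times that elsewhere (4 of 201 against 220 of 8734, Fisher's exact p = 0.820), with an interval of the odds ratio from 0.210 to 2.07 that leaves a modest excess open. For most of the 24, a fault or variant at single probes cannot be told apart from a real difference. Only 4 of them have another probe bright enough to compare. The median ratio between their other probes and the named one was 0.22, under the bound set beforehand for such a fault. With 4 genes this does not carry over to the rest of the 24. The ratios were 0.394 for Mbp, 0.04 for Slco4a1, -0.00 for Atp2c1 and 0.531 for Kcnab1. That of Kcnab1 came from 0.914 at the brighter probe, which repeats the fall, and 0.148 at a dim one. Position on the slide follows genotype throughout, and an effect of the genotype stays open.

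The second pattern is Plk1, at 9.52 on mutant replicate 3 and 6.59 to 6.68 on the other 3 mutant arrays, against 9.79 to 11.0 in the wild-type. Fewer dividing cells on those 3 arrays would lower other cell cycle genes as well, but 25 others showed a median gap of 0.10 between mutant arrays 1, 2 and 4 and array 3 (lowest -0.21, highest 0.49), against a gap of -2.89 for Plk1. Plk1 lies 90 genes from the nearer deleted gene, and a candidate explanation is a linked variant under its only probe that recombination removed from mutant replicate 3. That was not tested, since no second probe or genotype is at hand.

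The third pattern is the cell cycle list, lower in the mutant by a mean of -0.53 over 8 arrays, and -0.43 over the 25 genes other than Plk1. Without wild-type replicates 3 and 4 the mean was -0.11, and -0.017 ± 0.06 (SE) over the 25, so what is left there is mostly Plk1; this restates that the other genes were high on those arrays (list level 0.75 and 0.62). With the erythroid score as a covariate the mean was -0.25 ± 0.13 (SE). It stayed called by camera at the preset correlation of 0.01 (adjusted p = 0.00304). Over the 25 it was -0.15 ± 0.12 (camera adjusted p = 0.00671), which is closer to 0 than the dividing line of -0.22. Its error reaches across that line, a margin considered only after the first value was seen. With an estimated correlation camera did not call the list even on all arrays without the covariate (adjusted p = 0.666). For the cell cycle genes, differing amounts of red blood cell precursors and another property of that pair, such as a slightly younger stage, cannot be told apart. The erythroid level is raised on the same 2 arrays. Of the 11 erythroid genes 0 stand in another list, and the most abundant, Hba-a1 and Hbb-y, differ by 0.07 and 0.09 near the top of the scale. The nociceptive list was low on that pair (-0.94 and -0.67, elsewhere 0.09 to 0.46). The neural crest and progenitor list was high there (0.30 and 0.22, elsewhere -0.23 to 0.07). These opposite shifts argue against red blood cell precursors as the pair's only difference. They do not show which property moved the cell cycle genes. An effect of the genotype on division stays open. Cdk1 was also higher on wild-type replicates 1 and 2 (10.40 and 10.16) than on the mutant arrays (9.87 to 10.08). Top2a overlapped there, at 10.38 and 10.41 against 10.16 to 10.53. Both genes were picked after their values were seen.

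Mutant replicate 4 stood low for the glycolysis and hypoxia list at -0.13, with the other 3 mutant arrays at 0.13 to 0.18. The same array was low for Vim at 13.19 (others 13.48 to 13.50), Hey1 at 11.61 (others 11.85 to 11.86), Col4a1 at 11.94 (others 12.28 to 12.31) and Egfl7 at 10.70 (others 11.03 to 11.10). Wild-type replicate 3 stood high for Ctse at 8.61 (others 7.33 to 7.49) and for Alox12 at 8.93 (others 8.40 to 8.47). Atp2c1 was highest on wild-type replicate 1 at 7.06 (others 6.61 to 6.68). Tmem25 was highest on mutant replicate 3 at 8.75 (others 7.87 to 8.02). Tmem87a was high on wild-type replicate 2 at 8.31 (others 6.89 to 6.93). Irx3 was high on wild-type replicate 4 at 8.69 (others 7.61 to 7.75). Xist was low on mutant replicate 2 at 6.34 (others 8.90 to 9.13); wild-type replicate 4 was low too, at 6.39, and both arrays had the highest levels of the Y-linked Eif2s3y, 9.77 and 9.66, so each group holds 1 male-type array.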

How the results depend on the processing

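The 2 fits without a pair of wild-type arrays, the fit with the erythroid score and the cell cycle list without Plk1 were chosen after the data were seen. Of the called genes named by the rule, 0 changed sign in any setting; Etv4, Egr2, Dusp6, Etv1, Ntn5, Cldn34c1, Kcnab1, Plekhb1, Alox12, Hbb-b2, Atp2c1, Tmem25, Ccl19, Rnase4, Cdhr1 and Pkm kept the call in all alternatives run on them, while Nrg1 lost it in 11 of 22 and Tmem87a, Mbp, Art3 and Bbc3 in 10 each. Averaging a gene's probes used only those above the filter, which leaves out the other probes of Tmem25, Rnase4 and Alox12. The mean of the ERK outputs stayed between -0.47 and -0.30. Starting from 224 called genes (125 higher, 99 lower), median scaling gave 57 higher and 181 lower, the filter at the upper quartile, which tests fewer genes, gave 58 lower, and array weights gave 341 (200 higher). Relaxing the threshold to an adjusted p of 0.1 gave 443 (250 higher, 193 lower), and asking for 1.5-fold gave 127 (59 higher). Without wild-type replicates 1 and 2 there were 1218 (610 higher, 608 lower), which keep 210 of the 224. Leaving out 1 array gave 67 to 200 called genes, 29 to 114 higher and 38 to 95 lower, with fewer samples in each fit.

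With the replicate number as a replicate block 82 genes were called (37 higher, 45 lower), 78 of them among the 224, and camera called the glycolysis list (adjusted p = 0.0444). Arrays of the same number deviated from their group means with correlations of -0.08, -0.28, -0.07 and -0.05. This gives no sign that the numbers pair the samples, but it cannot exclude a weak litter effect shared by arrays of the same number.

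The glial list had means of -0.29 under median scaling (adjusted p = 0.0648), 0.035 with the upper quartile filter, where the sign turned (0.712), and -0.11 without wild-type replicates 1 and 2 (0.144), with -0.32 to -0.13 when 1 array was left out; adjusted p ranged from 0.00153 to 0.712 over its alternatives. The neuronal list had 0.031 with the erythroid score (0.465) and turned to -0.035 without wild-type replicates 3 and 4 (0.954), with 0.070 to 0.23 when 1 array was left out and 0.35 without wild-type replicates 1 and 2 (9.1e-06). By camera at the preset correlation of 0.01, the cell cycle list had -0.11 without wild-type replicates 3 and 4 (adjusted p = 0.517). It had -0.95 without replicates 1 and 2 (1.5e-21), and stayed called with the erythroid score (-0.25, 0.00304). Without Plk1 the first and last of these were -0.017 (0.698) and -0.15 (0.00671). With an estimated correlation the ERK (-0.42), glial (-0.21), neuronal (0.16) and cell cycle (-0.53) lists kept their means and lost the call, and the last 3 lost it by fry too. The cause was not tested for these changes, beyond what fewer samples or genes bring. No background correction and the authors' table are the same values here; both gave 238 genes. The normexp setting listed as an alternative to neqc became the setting reported, as neqc could not be run. Without detection p-values the signal over background of dim probes is not known.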

Other observations

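The neuropeptide genes, the boundary cap genes and the single genes below were chosen after their values were seen, or after Egr2 and Ntn5 were seen to fall, as were the tests on them except the boundary cap test, whose bounds were set before its values were seen. Among neuropeptide genes 3 of 8 tested fell in the mutant: Npy by -0.997 ± 0.20 (limma adjusted p = 0.0316, n = 4 per group), Vgf, a growth factor-induced peptide precursor, by -0.98 ± 0.14 (adjusted p = 0.00820) and Cartpt by -0.65 ± 0.13 (adjusted p = 0.0351). Gal and Sst stood at 1.57 ± 0.77 and -1.47 ± 0.76 and did not pass. The neuropeptide Y receptor gene Npy1r fell as well, at -0.53 (adjusted p = 0.00873). Single genes that rose include Tlx2 at 0.79 and Bcl11b at 0.64, both transcription factor genes (adjusted p = 0.00369 for each), the potassium channel gene Kcnc1 at 0.79 (adjusted p = 0.00451), the galanin receptor gene Galr2 at 0.77 (adjusted p = 0.00400) and Doc2b, a calcium sensor of vesicle release, at 0.84 (adjusted p = 0.00582). Spry3, of the Sprouty family of ERK inhibitors, fell by 0.74 (adjusted p = 0.00247). Npy1r, Vgf, Tlx2, Bcl11b, Kcnc1, Galr2, Doc2b and Spry3 are among the 61 genes called whichever array was left out; Npy and Cartpt are not.

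Wild-type replicates 3 and 4 stood apart from the other arrays in several single genes. Gal stood at 9.79 and 10.64 on these, and at 13.17 to 13.86 on the other 6 arrays. Th, the first enzyme of catecholamine synthesis, stood at 7.24 and 7.46 against 9.63 to 10.44, and Scn10a, a sodium channel gene of nociceptors, at 7.73 and 8.04 against 9.49 to 10.20. Sst went the other way, at 9.99 and 8.98 against 6.02 to 6.57, as did the embryonic globin gene Hbb-bh1, at 13.96 and 13.61 against 10.92 to 12.37, and the proneural gene Neurog2, at 7.45 and 7.94 against 6.35 to 7.01. The mutant arrays differed among themselves in skeletal muscle markers, at -0.56 and -0.66 on replicates 1 and 2 and 0.44 and 0.68 on replicates 3 and 4.

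Egr2 and Ntn5 both mark boundary cap cells, a neural crest derivative at the nerve entry points, and both fell. A hypothesis is that boundary cap markers fell as a set. The other 6 tested markers had a median difference of -0.18; 5 were lower and 0 were called, with Npr3 at -0.65 ± 0.15 (adjusted p = 0.0553), Hey2 at -0.56 ± 0.27, Maob at -0.24 ± 0.09 and Sema6a at 0.16 ± 0.09. The median lies between the level set for a shared fall (-0.25) and that set against it (-0.1), so these data do not decide.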
